A study of Kluyveromyces lactis with 17 samples.

How the data were processed

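RNA was measured by poly(A)-selected, paired-end sequencing of 150 bp reads in the yeast Kluyveromyces lactis. A wild-type strain (WT, MATa SIR2) and a strain lacking SIR2 (sir2Δ, MATα) were compared, and both lack the silent mating-type loci HML and HMR. Per the labels' protocols, cultures were grown overnight with 400 µg/L nicotinic acid, a precursor of NAD+, and then moved for 4 h to medium with 15, 45, 135 or 400 µg/L. The 2 strains were grown in parallel at each level. The series text states 2 independent biological replicates for each of the 8 groups, and 17 libraries were analysed. WT at 400 µg/L had 3 libraries, numbered 1, 1R and 2. Libraries 1 and 1R share a number, so they were treated as repeats of 1 replicate and their counts were summed, which left 16 columns in the fit. The labels mark libraries 1 and 1R and sir2Δ library 8 at 15 µg/L as resubmitted, without saying what was resubmitted.

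The deposited count table holds whole-number read counts for 5335 genes, and per the submitters' processing notes the tools used were FastQC, MultiQC, cutadapt, Bowtie2, SAMtools, featureCounts and DESeq2. Their versions, settings and order, the genome build, the annotation and the handling of strand and of reads with several matches are not given in the sources used here. Reads from near-identical genes, overlapping genes and antisense partners may therefore be shared or lost. The deposited normalized table holds a signal equal to those counts divided by 1 size factor per library, from the values themselves. The size factors recomputed by the median-of-ratios method gave back the counts to within 4.7e-09 reads. That table lists 5302 genes. The other 33 genes had at most 9 reads in all, and every listed gene had at least 10. It was used only for this check.

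Gene names came from a reference table of assembly ASM251v1, in which all 5335 identifiers matched and 4043 had a symbol. The table was used only for names, coding lengths and the order of genes along the 6 chromosomes, since no build is named for the counts, and no coordinates are given. Of the genes, 5084 are protein coding, and 97.8% of the gene lengths are multiples of 3, so lengths are called coding lengths. The table gives KLLA0_F14663g no symbol. It was taken as K. lactis SIR2 from prior knowledge of the gene, and the α mating-type genes of the list were matched to HMLALPHA1 and HMLALPHA2.

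Total counts per library ranged from 24663143 to 38246270 reads, with a median of 33734530. At this depth a count of 0 allows up to 3 reads, which is 0.0784 to 0.122 CPM (read counts scaled to a fixed library total) in a library. Such limits cover counting error only, because the reads carry no molecular identifiers. Ribosomal RNA took 1.36% to 10.6% of the counts, and mitochondrial genes took 0.0176% to 0.0811%.

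Genes were tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood test with robust estimation, on the deposited counts. Genes were kept with filterByExpr at a minimum count of 10, which left 5224 and removed 111. Libraries were scaled by TMM factors, and CPM values use these factors. A model with 1 mean for each of the 8 groups was fitted over all 16 columns, so that all groups shared 1 estimate of the spread with 8 residual degrees of freedom. The common biological coefficient of variation was 0.0857. The 12 comparisons were sir2Δ against WT at each of the 4 levels and averaged over them, each lower level against 400 µg/L within each strain, and the interaction, which is the change from 400 to 15 µg/L in sir2Δ minus that in WT. Adjusted p-values are Benjamini-Hochberg values over the 5224 genes, and a gene is called at an adjusted p under 0.05. Fold changes are on the log2 scale with a prior count of 0.125 and are given ± SE, which was computed from the estimate and its F statistic. CPM values are means ± SD over 2 replicates. Fold changes of genes with few reads in 1 group depend on the prior count.

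Gene lists were written before the data were examined. They cover NAD salvage and transport, NAD de novo synthesis, silencing factors and sirtuins, a-specific and α-specific genes, the mating pathway, early meiosis, middle and late sporulation, thiamine and pyridoxine synthesis, lactose and galactose use, sugar transport and sensing, glycolysis and fermentation, NAD-linked redox enzymes, the TCA cycle and respiration, gluconeogenesis with the glyoxylate and carnitine pathways, the general stress response, iron uptake, phosphate starvation, amino acid synthesis, nitrogen catabolism and permeases, the cell surface, drug and metal efflux, histones and replication, ribosome biogenesis, ribosomal proteins, and genes near chromosome ends. SIR2 itself was kept out of the list tests. The lists were written from S. cerevisiae names, so a K. lactis gene without a symbol could not enter them, except by position. The 25 lists with at least 3 measured members were tested in 5 comparisons with camera of limma 3.58.1, which compares a list with all other genes, at a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry were run beside it, and p-values were adjusted over the lists of a comparison. The plan took genes within 25 kb of a chromosome end, or the 15 nearest to each end by order without usable coordinates. The 25 kb test was not run. The reference gives positions, but no build is named for the counts, so they served for gene order alone. Genes near chromosome ends are therefore the 15 nearest to each of the 12 ends by order. They were compared with the other genes by two-sided Fisher's exact tests. Those tests treat genes as independent, while neighbouring and near-identical genes may change together.

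The genes named in the text were chosen by a rule set before the data were examined. For sir2Δ against WT at 400 and at 15 µg/L, for 15 against 400 µg/L in each strain and for the interaction, it takes up to 12 genes with the largest rise and 12 with the largest fall. These must be called, reach 5 CPM in the higher group and have every replicate of 1 group above every replicate of the other, a condition dropped for the interaction. SIR2, the a-specific and α-specific genes are always named, all members of the NAD salvage and silencing lists may be named, and from each other list up to 4 members with the smallest adjusted p are used. Values of these genes in further comparisons are given beside them.

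Because both comparisons use the WT libraries at 400 µg/L, the overlap of the WT response with the strain difference was set beside 30 simulations of unchanged groups and beside the overlap of independent lists, and was repeated with the strain difference at 135 µg/L, which shares no library. The fit was tested on simulated counts with 100 genes changed by each of 2 sizes. The counts were drawn from the mean levels of WT at 400 µg/L with the spread of the real fit. Changed genes had at least 5 CPM. No coding length trend was simulated, so the recovery below holds for data without one. At a log2 change of 1 it recovered 99% of 100 genes for WT at 15 against 400 µg/L, 98% for sir2Δ against WT at 400 µg/L and 91% for the interaction, and at a log2 change of 2 it recovered 100%, 98% and 99%. Of its calls 6.57%, 6.67% and 4.04% were unchanged genes, so the first pair lay above the 5% aimed for. The alternatives were other scaling factors, other filters, DESeq2 1.42.0, a fit on only the groups compared, blocks by library number, other treatments of libraries 1, 1R and the resubmitted libraries, a fold change minimum and leaving out each library. Alternatives chosen after the data were seen were the removal of a coding length trend, other numbers of genes per end, end genes without near-identical families or without the 3 genes that the reference places at or beside HML, and the overlap without library 1. Figures were drawn with matplotlib.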

Results

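Transcript levels were measured in K. lactis WT and sir2Δ cells at 4 levels of nicotinic acid, the vitamin from which this yeast makes NAD+. SIR2 encodes an NAD+-dependent protein deacetylase that silences chromatin in budding yeasts. The series title frames the question of how far Sir2 carries the transcriptional response to low NAD+. Each of the 8 groups had 2 replicates, and WT at 400 µg/L had 3 libraries that made up 2 replicates. Total counts ranged from 24663143 to 38246270 reads per library. The 2 strains also differ in mating type, so a difference between strains is one of SIR2 and mating type together.

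Replicate libraries had Pearson correlations of log2 CPM across genes of 0.990 to 0.998, except for library 1 of WT at 400 µg/L. This library had r = 0.949 with library 1R and 0.955 with library 2, while 1R and 2 had 0.996. Its log2 difference from the mean of 1R and 2 fell with coding length, from a median of 0.62 in the shortest of 5 length bins to -0.41 in the longest. Chi-square per degree of freedom between replicate libraries was 6.12 or more in every pair, so no library was a copy of another within sampling noise. The first principal component held 64.9% of the variance and separated the strains, with sir2Δ libraries at -24.9 to -19.8 and WT libraries at 8.98 to 29.9. WT at 15 µg/L lay nearest to sir2Δ on it, at 10.1 and 8.98.

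**Figure D1:**
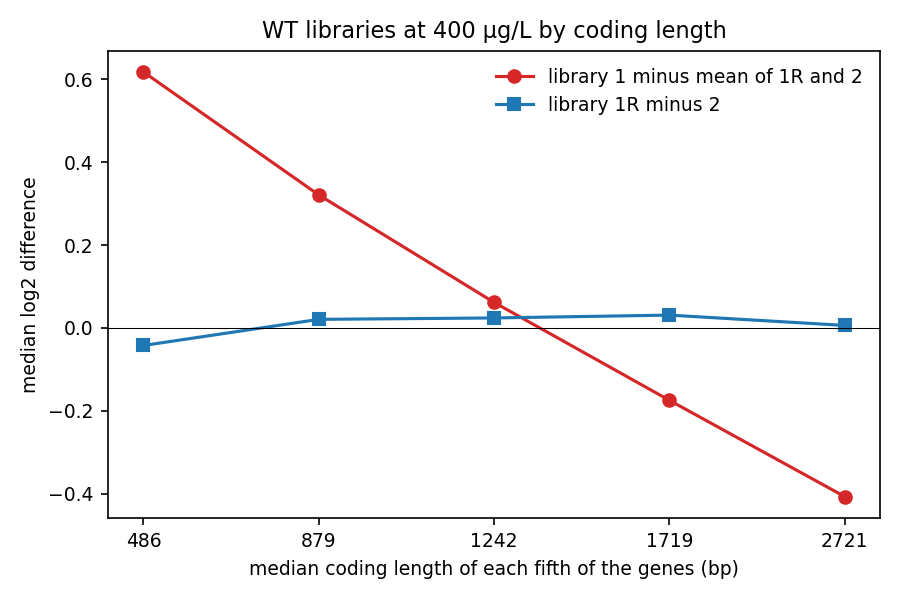
Median log2 difference between libraries of WT at 400 µg/L (vertical axis) by 5 bins of coding length in bp (horizontal axis), for library 1 against the mean of 1R and 2 and for 1R against 2. The first falls from 0.62 at a median length of 486 bp to -0.41 at 2721 bp, and the second stays between -0.04 and 0.03.

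The deleted gene was checked first. SIR2 (KLLA0_F14663g) had 140 ± 5.61 CPM in the WT replicates (SD, n = 8, range 128 to 145) and 1.37 ± 0.730 CPM in the sir2Δ replicates (n = 8, range 0.687 to 2.64), 0.977% of the WT level. Its log2 fold change in sir2Δ against WT was -5.89 ± 0.19 at 400 µg/L and -7.48 ± 0.21 at 15 µg/L (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 6.4e-13 and 1.5e-12). In WT it did not pass the test between 15 and 400 µg/L, with a log2 fold change of 0.11 ± 0.13. The change of -1.48 between these levels within sir2Δ rests on 23 to 77 reads per library.

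The α genes also followed the labels, while the other measured members of the a-specific and α-specific lists did so in part or not at all. The α genes HMLALPHA1 and HMLALPHA2, which encode regulators of α-cell identity, had 75.9 ± 2.52 and 23.0 ± 2.28 CPM in sir2Δ (n = 8) and 0.543 ± 0.382 and 0.182 ± 0.120 CPM in WT. Their neighbour KLLA0_C00396g had 81.6 ± 10.3 and 0.699 ± 0.539 CPM. Libraries 1 and 1R of WT at 400 µg/L had 1.66% and 2.12% of the sir2Δ mean at 400 µg/L for HMLALPHA1, against 0.432% in library 2. In the other direction, KLLA0_C03135g and KLLA0_B14553g had means of 16.6 and 17.1 CPM in WT (ranges 12.5 to 21.5 and 12.9 to 22.6, n = 8) and 0.134 and 0.142 CPM in sir2Δ. KLLA0_C03157g and KLLA0_B14575g rose in WT from means of 4.92 and 4.88 CPM at 400 µg/L to 47.7 and 49.7 CPM at 15 µg/L. In sir2Δ at 15 µg/L they had 2 and 1, and 3 and 2 reads in the 2 libraries. The levels run so close within each of these pairs that reads may be shared between near-identical copies, and the split between members is uncertain. Over the 4 levels, sir2Δ had 112% of the WT mean for STE3, 94.0% for SAG1 and 108% for ASG7. Of the a-specific genes, AGA2 was higher in sir2Δ, against its labelled MATα type, at 400 (3.01 ± 0.17) and at 15 µg/L (1.30 ± 0.16). BAR1 (1.90 ± 0.12 and -0.43 ± 0.11) and AXL1 (0.78 ± 0.13 and -0.79 ± 0.12) were higher at 400 and lower at 15 µg/L. STE2 had 67.2 CPM in WT at 15 µg/L and 20.6 in sir2Δ, but 24.5 and 20.6 at 400 µg/L.

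In WT, lowering nicotinic acid from 400 to 15 µg/L raised the genes that bring the vitamin into NAD+ synthesis. TNA1, the nicotinic acid permease, rose from 424 ± 21.9 to 3353 ± 31.1 CPM, a log2 fold change of 2.98 ± 0.10. NPT1, the nicotinate phosphoribosyltransferase that begins salvage, rose from 151 ± 11.3 to 1211 ± 25.4 CPM, a fitted fold of 8.02 (edgeR quasi-likelihood test, adjusted p = 2.8e-13). URH1, a nucleosidase that acts on nicotinamide riboside, rose by 0.94 ± 0.08. QNS1, the NAD synthetase, rose by 0.75 ± 0.08, and the nucleoside transporter FUN26 by 0.63 ± 0.09. Of the 14 measured members of the NAD salvage and transport list, 5 rose and 2 fell (5 higher and 3 lower adjusted over the list alone), with a mean of 0.55 and a median of 0.11 (camera, adjusted p = 6.9e-05, and adjusted p = 0.0403 with an estimated correlation). The de novo list had 1 measured member, BNA3, a kynurenine aminotransferase, at 0.05 ± 0.07, which did not pass the test. In all, 823 genes rose and 539 fell between 15 and 400 µg/L, of which 201 rose and 17 fell by at least 1 log2 unit. Rises made up 60.4% of these calls, and 50.0% with upper-quartile scaling factors, and without WT library 7 at 15 µg/L 841 genes were called in place of 1362. Without library 1 of WT at 400 µg/L the count was 1584, and 1160 of the 1362 calls were shared in the same direction.

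The number of genes called in WT grew with each step from 400 to 15 µg/L. At 135 µg/L 116 genes rose and 45 fell against 400 µg/L, and at 45 µg/L 376 rose and 181 fell. TNA1 was already higher at 135 µg/L by 1.23 ± 0.09 and at 45 µg/L by 2.58 ± 0.10, and NPT1 by 0.34 ± 0.08 and 1.64 ± 0.08. Of the 201 genes that rose by at least 1 at 15 µg/L, 142 had means that increased at every step. Their selection already sets 15 above 400 µg/L, and no expected number was computed. The medians of the 201 were 0.20, 0.73 and 1.80 at 135, 45 and 15 µg/L. Of the 201, 45 were called as rises at 135 µg/L and 138 at 45 µg/L. With upper-quartile factors the share of rises was 61.5% in place of 72.0% at 135 µg/L and 56.0% in place of 67.5% at 45 µg/L. The counts of all genes called at 45 and 135 µg/L depended on single libraries. Without library 1 of WT at 400 µg/L, 454 of the 557 calls at 45 µg/L and 122 of the 161 at 135 µg/L were shared. At 45 µg/L 319 genes were called in place of 557 without WT library 6 at that level, 350 without library 1R and 364 without libraries 1 and 1R. At 135 µg/L 39 or 35 were called in place of 161 without WT library 3 or 4 at that level, 75 without 1R, 86 without 1 and 1R, and 293 without WT library 2.

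**Figure D2:**
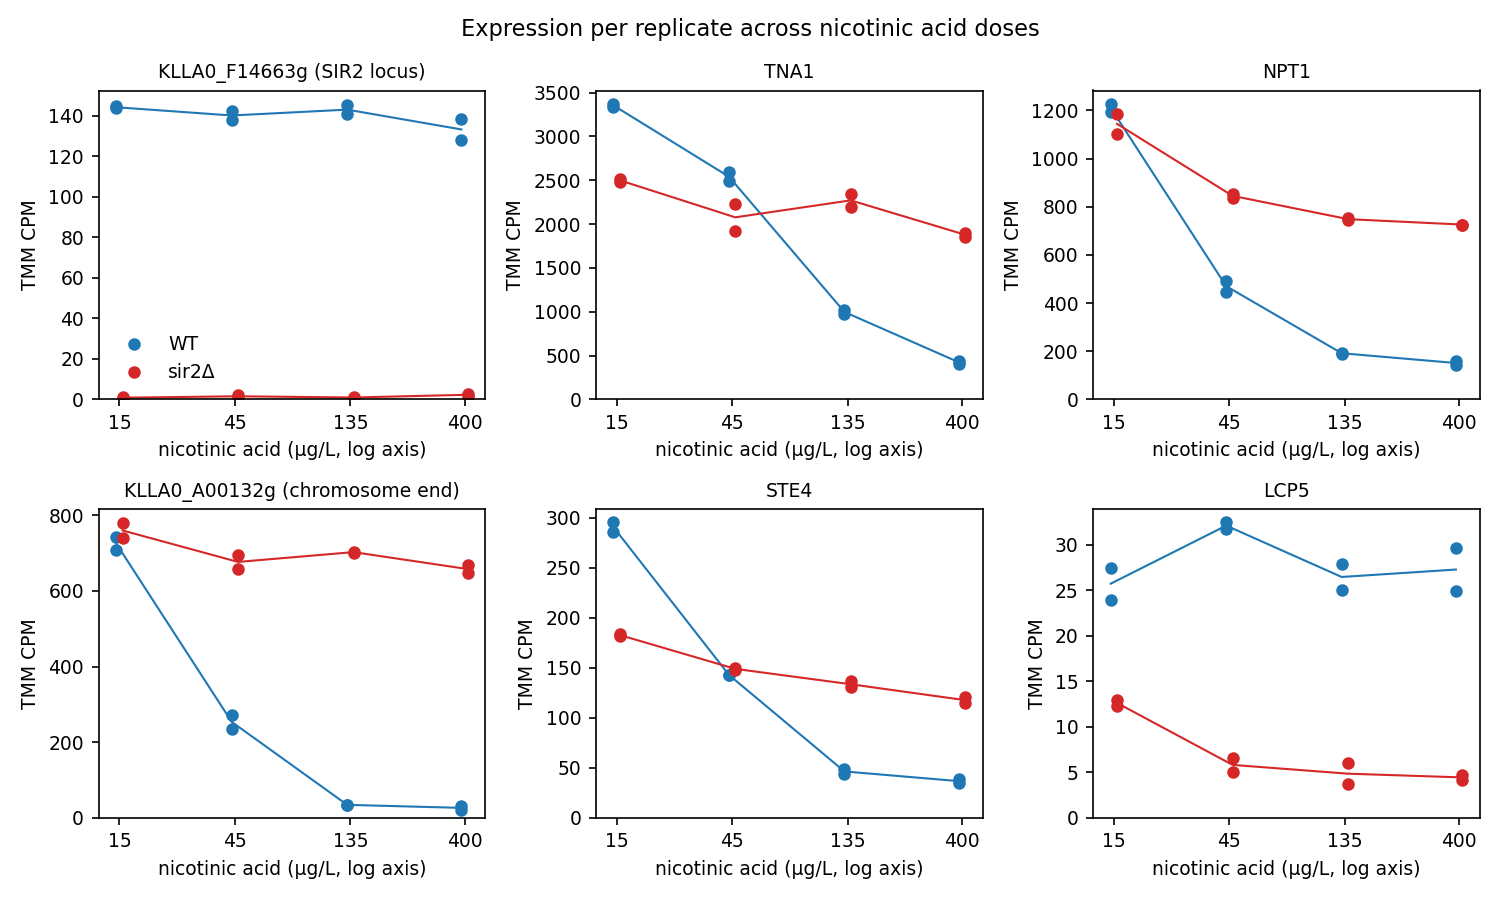
CPM per replicate (vertical axis, TMM-scaled) against nicotinic acid in µg/L (horizontal log axis) for KLLA0_F14663g (SIR2), TNA1, NPT1, KLLA0_A00132g, STE4 and LCP5, with WT in blue, sir2Δ in red and lines through the means of 2 replicates. TNA1 rises in WT from 424 to 3353 CPM as the level falls and lies between 1878 and 2499 CPM in sir2Δ.

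The largest rises in WT at 15 µg/L were in genes at chromosome ends. KLLA0_A00132g rose from 26.3 ± 7.14 to 725 ± 25.7 CPM, a log2 fold change of 4.77 ± 0.15. The other end genes among the 12 largest were KLLA0_F00154g (4.57), KLLA0_B00143g (4.55), KLLA0_D00143g (4.50), KLLA0_E00133g (4.48), KLLA0_C00132g (4.26), KLLA0_D20009g (4.13), KLLA0_A00110g (4.09), KLLA0_E00111g (4.03), KLLA0_D20031g (4.02) and KLLA0_F00132g (3.98). These 11 genes are the first or the second from an end, and they belong to families with near-identical expression profiles that may share reads. The remaining gene of the 12, KLLA0_F22319g, rose by 3.98 ± 0.17 and lies away from the ends. Of the 178 tested genes among the 15 nearest to each end, 100 rose (56.2%) against 14.3% of the other genes, and 10 fell. The odds ratio for rises was 7.66 (95% interval 5.58 to 10.6, two-sided Fisher's exact test, p = 1.2e-36, or 5.8e-36 adjusted over 10 such tests). Without the 17 genes of near-identical families the odds ratio was 6.36, and it was 12.1 with 8 genes per end and 4.06 with 30. Camera gave an adjusted p of 6.1e-31 for the list, and adjusted p = 0.000351 with an estimated correlation (107 higher and 11 lower adjusted over the list alone). Of the 60 genes in ranks 1 to 5, 46 rose with a median of 1.56, and the median was 0.07 in ranks 16 to 20.

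Genes of mating and sporulation rose as well in WT. Of the 6 a-specific genes, 5 rose and 0 fell (5 higher and 0 lower adjusted over the list alone), with a median of 1.53 (camera, adjusted p = 3.9e-07, and adjusted p = 0.00675 with an estimated correlation). BAR1, the protease that degrades α-factor, rose by 2.19 ± 0.12, the agglutinin subunit AGA2 by 1.72 ± 0.18 and the endoprotease AXL1 by 1.61 ± 0.13. The α-factor receptor STE2 rose by 1.46 ± 0.10 and the a-factor exporter STE6 by 0.32 ± 0.10. ASG7 had 0.22 ± 0.18 and did not pass the test. In the mating pathway 10 of 25 members rose and 3 fell (11 higher and 3 lower adjusted over the list alone), led by the G-protein subunits STE4 (2.99 ± 0.08), GPA1 (2.89 ± 0.12) and STE18 (2.37 ± 0.20). The camera adjusted p was 8.8e-04, and adjusted p = 0.101 with an estimated correlation. Of 38 middle and late sporulation genes 18 rose and 1 fell (18 higher and 3 lower adjusted over the list alone; camera, adjusted p = 7.8e-08, and adjusted p = 0.0314 with an estimated correlation), among them RRT8 (3.14 ± 0.12) and the spore wall genes OSW2 (2.61 ± 0.10) and CRR1 (2.15 ± 0.12). Early meiosis genes did not pass as a list (6 rose and 4 fell of 24, 8 higher and 4 lower adjusted over the list alone; camera, adjusted p = 0.120), although IME1, the inducer of meiosis, rose by 1.59 ± 0.11 and ZIP2 by 1.39 ± 0.12.

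Amino acid synthesis and phosphate genes rose in WT at 15 µg/L and galactose genes fell. Of 75 members 45 rose and 3 fell (47 higher and 5 lower adjusted over the list alone), with a median of 0.42 (camera, adjusted p = 3.4e-10, and adjusted p = 0.0403 with an estimated correlation). They include the aspartate kinase HOM3 (1.14 ± 0.07), CPA1 of arginine synthesis (1.09 ± 0.07), TRP3 (1.10 ± 0.07) and HIS5 (1.10 ± 0.08). In the phosphate list 9 of 16 rose and 2 fell (9 higher and 2 lower adjusted over the list alone), with SPL2, a regulator of phosphate uptake, at 3.10 ± 0.11, PHO92, an RNA-binding protein, at 2.22 ± 0.11 and the transcription factor PHO4 at 1.40 ± 0.10. Its camera adjusted p was 5.5e-05, and adjusted p = 0.0796 with an estimated correlation. Galactose genes fell, 4 of 5 (0 higher and 4 lower adjusted over the list alone), with a median of -0.81 (camera, adjusted p = 1.3e-04, and adjusted p = 0.0245 with an estimated correlation). These were the Leloir pathway genes GAL10 (-1.37 ± 0.13), GAL1 (-1.02 ± 0.09) and GAL7 (-0.81 ± 0.10) and the repressor GAL80 (-0.61 ± 0.09). Of 127 ribosome biogenesis genes 3 rose and 12 fell (1 higher and 8 lower adjusted over the list alone), with a median of -0.12 (camera, adjusted p = 0.0171, and adjusted p = 0.534 with an estimated correlation). The other named falls were KLLA0_A11110g (-2.22), KLLA0_B14839g (-1.26), KLLA0_F07887g (-1.24), KLLA0_C18117g (-1.19), KLLA0_B14883g (-1.19), RDS2 (-1.06) and ECT1 (-1.04). Those of KLLA0_B14861g (-1.30), KLLA0_E09021g (-1.29) and ACS1 (-1.10) lost their call without single WT libraries. For ACS1 the edgeR adjusted p was 0.102 without library 2 at 400 µg/L, 0.113 without libraries 1 and 1R, and 0.131 and 0.107 without library 7 or 8 at 15 µg/L. For KLLA0_B14861g it was 0.169 without library 2, 0.407 without 1R, and 0.0855 and 0.114 without library 7 or 8, and for KLLA0_E09021g it was 0.0664 without library 2.

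The comparison at 400 µg/L asked how sir2Δ differed from WT with the most nicotinic acid, and TNA1 and NPT1 were higher in sir2Δ. TNA1 had 1878 ± 32.4 CPM in sir2Δ and 424 ± 21.9 in WT (2.15 ± 0.09), and NPT1 had 726 ± 0.274 and 151 ± 11.3 CPM (2.27 ± 0.08). URH1 was higher by 1.10 ± 0.08 and FUN26 by 0.83 ± 0.09, while the nicotinamide riboside kinase NRK1 was lower (-0.94 ± 0.26), as was MEU1 (-0.77 ± 0.10). Of the 14 NAD salvage and transport genes 8 were higher and 2 lower (8 higher and 3 lower adjusted over the list alone; camera, adjusted p = 0.00158, and adjusted p = 0.0911 with an estimated correlation). BNA3, the only measured member of the de novo list, was higher by 0.69 ± 0.07. Over all genes 1174 were higher and 1163 lower, of which 236 and 243 differed by at least 1 log2 unit. Upper-quartile factors moved the median of all genes by -0.10 and the share of higher calls from 50.2% to 34.7%. Without library 1 of WT the count was 2921 in place of 2337, and 2206 of the 2337 calls were shared.

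Genes near chromosome ends were higher in sir2Δ at 400 µg/L. Of the 178, 110 were higher in sir2Δ (61.8%) against 1057 of 5033 other genes, and 16 were lower. The odds ratio was 6.08 (4.42 to 8.42, two-sided Fisher's exact test, p = 1.2e-30, adjusted p = 4.0e-30). Camera gave an adjusted p of 5.4e-27, and adjusted p = 0.000362 with an estimated correlation (112 higher and 18 lower adjusted over the list alone). KLLA0_A00110g (4.67 ± 0.16), KLLA0_D20031g (4.65 ± 0.16), KLLA0_A00132g (4.63 ± 0.15) and KLLA0_E00111g (4.59 ± 0.12), each the first or second gene from an end, were among the 12 largest rises. The odds ratio was 9.86 with 8 genes per end, 2.91 with 30, and 5.14 without near-identical families. HMLALPHA2 (6.42 ± 0.31), HMLALPHA1 (6.19 ± 0.26) and KLLA0_C00396g (5.72 ± 0.31) are also among the 12. The reference places them at ranks 12 to 14 from an end, at or beside HML, which the labels state was deleted in both strains, so their reads need not come from there. Without these 3 genes, a choice made after the data were seen, 107 of 175 were higher and the odds ratio was 5.92. The others were KLLA0_A05687g (5.52 ± 0.35), KLLA0_C17226g (5.28 ± 0.22), KLLA0_D13288g (5.14 ± 0.39), KLLA0_F05379g (5.09 ± 0.24) and KLLA0_F24596g (4.66 ± 0.18), all away from the ends. Ranks 1 to 5 from an end had 49 of 60 genes higher with a median of 1.86, and ranks 16 to 20 had a median of -0.00.

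**Figure D3:**
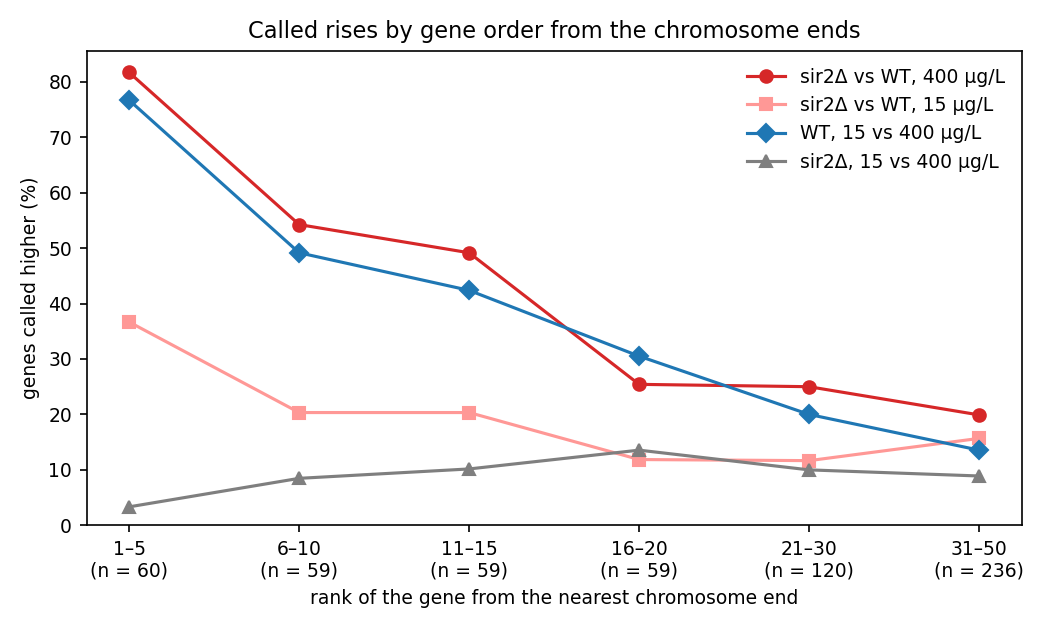
Percent of tested genes called higher (vertical axis) by rank from the nearest chromosome end (horizontal axis, ranks 1 to 5 up to 31 to 50) in 4 comparisons. In ranks 1 to 5, 49 of 60 genes were higher in sir2Δ than WT at 400 µg/L, 46 rose in WT at 15 µg/L and 2 rose in sir2Δ at 15 µg/L.

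Sporulation and mating genes were higher in sir2Δ at 400 µg/L. Of 38 middle and late sporulation genes 21 were higher and 3 lower (22 higher and 3 lower adjusted over the list alone), with a median of 0.55 (camera, adjusted p = 2.7e-11, and adjusted p = 0.0122 with an estimated correlation). Among them were RRT8 (3.72 ± 0.12), CRR1 (2.66 ± 0.12), OSW2 (2.59 ± 0.10) and the dityrosine exporter DTR1 (1.87 ± 0.08). Early meiosis genes counted 10 higher and 1 lower of 24 (10 higher and 1 lower adjusted over the list alone), with MUM2 at 1.73 ± 0.11 and IME1 at 1.60 ± 0.11 (camera, adjusted p = 0.0208, and adjusted p = 0.305 with an estimated correlation). The a-specific AGA2 (3.01 ± 0.17), BAR1 (1.90 ± 0.12) and AXL1 (0.78 ± 0.13) were higher and STE6 was lower (-0.26 ± 0.10), while STE2 (-0.24 ± 0.11) and ASG7 (0.09 ± 0.19) did not pass the test. That made 3 higher and 1 lower of 6 (3 higher and 2 lower adjusted over the list alone; camera, adjusted p = 0.0209, and adjusted p = 0.101 with an estimated correlation). The α-specific list had 3 of 4 higher and 0 lower (3 higher and 0 lower adjusted over the list alone; camera, adjusted p = 2.3e-06, and adjusted p = 0.00710 with an estimated correlation). Its called members were HMLALPHA1 and HMLALPHA2, which the MATα genotype of sir2Δ sets, and the a-factor receptor STE3 (0.28 ± 0.09), with SAG1 at -0.17 ± 0.12. In the mating pathway 13 of 25 were higher and 2 lower (13 higher and 2 lower adjusted over the list alone), with STE18 at 2.95 ± 0.20, GPA1 at 2.39 ± 0.12, STE4 at 1.68 ± 0.08 and PRM1 at 1.39 ± 0.15 (camera, adjusted p = 0.00742, and adjusted p = 0.168 with an estimated correlation).

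Ribosome biogenesis genes were lower in sir2Δ at 400 µg/L. All but 1 of the 127 members were called lower and 0 higher (0 higher and 127 lower adjusted over the list alone), with a median of -1.43 (camera, adjusted p = 3.0e-68, and adjusted p = 0.00136 with an estimated correlation). The log2 fold change was -2.61 ± 0.19 for LCP5, -2.34 ± 0.13 for NOP4, -2.33 ± 0.20 for RRP1, -2.24 ± 0.12 for REI1, -2.19 ± 0.13 for the helicase DBP9, -2.19 ± 0.28 for CGR1, -2.08 ± 0.10 for RLP24 and -1.82 ± 0.09 for TSR1, which act in the assembly of ribosomal subunits. The other named falls, apart from the deleted SIR2, were KLLA0_C03135g (-5.86 ± 0.39), KLLA0_B14553g (-5.66 ± 0.30), RBP95 (-2.62 ± 0.20), CCM1 (-2.55 ± 0.18) and KLLA0_F07887g (-2.20 ± 0.21). Those of KLLA0_C03135g and KLLA0_B14553g rest on few sir2Δ reads. Of the 243 genes lower by at least 1 log2 unit, 104 were on this list. Ribosomal protein genes did not pass as a list (1 higher and 3 lower of 57, 0 higher and 0 lower adjusted over the list alone; camera, adjusted p = 0.797), and without library 1 of WT 18 were higher and 1 lower.

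Several lists of metabolism and stress passed toward higher values in sir2Δ at 400 µg/L, with the preset correlation alone. The sugar transport and sensing list did not pass, with 3 higher and 1 lower of 6 (3 higher and 1 lower adjusted over the list alone; camera, adjusted p = 0.780). Of 12 glycolysis genes 10 were higher and 0 lower (10 higher and 0 lower adjusted over the list alone), such as GPM1 (0.95 ± 0.11), TPI1 (0.92 ± 0.11) and FBA1 (0.88 ± 0.10) (camera, adjusted p = 0.00532, and adjusted p = 0.310 with an estimated correlation). The TCA cycle and respiration list had 23 higher and 1 lower of 43 (24 higher and 1 lower adjusted over the list alone; camera, adjusted p = 0.00637, and adjusted p = 0.310 with an estimated correlation), with CIT3 at 2.54 ± 0.30. NAD-linked redox enzymes had 20 higher and 1 lower of 33 (21 higher and 2 lower adjusted over the list alone), with ALD4 at 0.90 ± 0.10 (camera, adjusted p = 0.00187, and adjusted p = 0.127 with an estimated correlation). The gluconeogenesis list had 10 higher and 3 lower of 23 (10 higher and 3 lower adjusted over the list alone; camera, adjusted p = 0.0227, and adjusted p = 0.384 with an estimated correlation), with isocitrate lyase ICL1 at 2.36 ± 0.11 and the acyl-CoA oxidase POX1 at 1.92 ± 0.14. All 5 galactose genes were higher (5 higher and 0 lower adjusted over the list alone; camera, adjusted p = 0.0181, and adjusted p = 0.101 with an estimated correlation), including GAL10 (1.00 ± 0.12). Thiamine genes had 4 higher and 1 lower of 10 (4 higher and 1 lower adjusted over the list alone; camera, adjusted p = 0.00873, and adjusted p = 0.0829 with an estimated correlation), with THI2, an activator of thiamine genes, at 2.38 ± 0.12. Phosphate genes had 8 higher and 2 lower of 16 (9 higher and 2 lower adjusted over the list alone; camera, adjusted p = 0.00532, and adjusted p = 0.187 with an estimated correlation), with SPL2 at 3.33 ± 0.11. Stress genes had 17 higher and 2 lower of 29 (18 higher and 3 lower adjusted over the list alone; camera, adjusted p = 0.0240, and adjusted p = 0.232 with an estimated correlation), with the glycogen branching enzyme GLC3 at 0.75 ± 0.07.

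At 15 µg/L 768 genes were higher and 837 lower in sir2Δ than in WT, with 77 and 56 of them by at least 1 log2 unit. TNA1 was lower in sir2Δ (-0.42 ± 0.09) and NPT1 did not pass the test (-0.08 ± 0.08). Of the NAD salvage list 3 of 14 were higher and 2 lower (3 higher and 2 lower adjusted over the list alone; camera, adjusted p = 0.420), with ISN1 at 0.73 ± 0.07 and the nicotinamidase PNC1 at -0.30 ± 0.08. Genes near chromosome ends did not pass as a list (46 higher and 22 lower of 178, 50 higher and 24 lower adjusted over the list alone). Camera gave an adjusted p of 0.0816, and adjusted p = 0.350 with an estimated correlation. Of these genes 25.8% were higher against 14.3% of other genes (odds ratio 2.09, two-sided Fisher's exact test, p = 8.5e-05, adjusted p = 0.000169). Fisher's test treats genes as independent. The odds ratio was 1.95 without the 3 genes placed at HML, 2.98 with 8 genes per end and 1.37 with 30 (Fisher's exact test, adjusted p = 0.0426). The count of 1605 genes fell to 1029 without library 1R of WT at 400 µg/L, which enters only through the shared spread, to 1041 without sir2Δ library 8 and to 1044 without WT library 7 at 15 µg/L. At 135 and 45 µg/L 860 and 1092 genes were higher in sir2Δ and 801 and 977 lower, and at 135 µg/L 1083 in place of 1661 were called without sir2Δ library 4 and 1102 without WT library 3. Averaged over the 4 levels, 1616 genes were higher and 1579 lower. With upper-quartile factors the lower genes were the more frequent, at 924 against 772 at 135 µg/L, 1097 against 946 at 45 µg/L and 1869 against 1317 on average.

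The largest falls and rises at 15 µg/L are named here. KLLA0_C03157g (-9.87), KLLA0_B14575g (-9.23), KLLA0_B14553g (-8.78) and KLLA0_C03135g (-7.52) were lower in sir2Δ, with fold changes that rest on few sir2Δ reads, as was the deleted SIR2 (-7.48). KLLA0_C00396g (7.85 ± 0.39), HMLALPHA1 (7.65 ± 0.31) and HMLALPHA2 (6.89 ± 0.35) were higher in sir2Δ. In the α-specific list only these HMLALPHA genes, which the genotype sets, were called of 4 members (2 higher and 0 lower adjusted over the list alone), and STE3 (0.17 ± 0.09) and SAG1 (-0.11 ± 0.12) did not pass the test. Further rises were KLLA0_A05687g (3.62), KLLA0_B09064g (3.39), KLLA0_F24596g (3.15), KLLA0_C17226g (2.78), KLLA0_A00242g (2.68), KLLA0_D13288g (2.37), KLLA0_B10219g (2.25), the citrate synthase gene CIT3 (2.28) and AFB1 (2.63 ± 0.17), which in S. cerevisiae is an α-cell barrier to a-factor. STE2 was lower (-1.70 ± 0.11), as were AXL1 (-0.79 ± 0.12) and STE6 (-0.70 ± 0.10), while AGA2 was higher (1.30 ± 0.16), so that 4 of 6 a-specific genes were lower and 1 higher (1 higher and 4 lower adjusted over the list alone; camera, adjusted p = 0.00905, and adjusted p = 0.0626 with an estimated correlation). The other falls were KLLA0_C16225g (-2.13), KLLA0_F01595g (-1.92), KLLA0_D02442g (-1.49) and 3 genes without a protein product, the ribosomal RNA genes KLLA0_D17809r (-1.80) and KLLA0_D17935r (-1.60) and the transfer RNA gene KLLA0_B06996r (-1.74). These 3 had group means of 1.68 to 8.67 CPM at 15 µg/L. The libraries were selected for poly(A) RNA, and how evenly they retained such RNAs was not tested.

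Ribosome biogenesis genes were lower in sir2Δ at 15 µg/L, 110 of 127 with 1 higher (1 higher and 117 lower adjusted over the list alone) and a median of -0.63 (camera, adjusted p = 5.0e-30, and adjusted p = 0.0289 with an estimated correlation). Gluconeogenesis and glyoxylate genes were higher, 16 of 23 with 1 lower (16 higher and 1 lower adjusted over the list alone; camera, adjusted p = 5.4e-11, and adjusted p = 0.0466 with an estimated correlation), with ICL1 at 2.06 ± 0.11, POX1 at 1.59 ± 0.14 and malate synthase MLS1 at 1.04 ± 0.10. NAD-linked redox enzymes had 19 higher and 2 lower of 33 (20 higher and 2 lower adjusted over the list alone; camera, adjusted p = 4.0e-07, and adjusted p = 0.0402 with an estimated correlation), and galactose genes 3 higher and 0 lower of 5 (3 higher and 0 lower adjusted over the list alone; camera, adjusted p = 3.9e-04, and adjusted p = 0.0370 with an estimated correlation). Glycolysis had 10 higher and 0 lower of 12 (10 higher and 0 lower adjusted over the list alone; camera, adjusted p = 1.1e-04, and adjusted p = 0.215 with an estimated correlation). The TCA cycle list had 16 higher and 1 lower of 43 (19 higher and 1 lower adjusted over the list alone; camera, adjusted p = 3.9e-04, and adjusted p = 0.215 with an estimated correlation). Sporulation genes had 15 higher and 3 lower of 38 (15 higher and 3 lower adjusted over the list alone; camera, adjusted p = 3.8e-05, and adjusted p = 0.0626 with an estimated correlation), such as the septin SPR3 (1.73 ± 0.11). Stress genes had 14 higher and 4 lower of 29 (16 higher and 4 lower adjusted over the list alone; camera, adjusted p = 0.0245, and adjusted p = 0.215 with an estimated correlation). Iron genes were lower in 8 of 23 and higher in 1 (2 higher and 8 lower adjusted over the list alone), such as the pulcherrimin gene PUL3 (-1.29 ± 0.09) and the multicopper oxidase FET3 (-0.77 ± 0.08) (camera, adjusted p = 0.00746, and adjusted p = 0.215 with an estimated correlation). Histone and replication genes had 10 higher and 14 lower of 31 (10 higher and 16 lower adjusted over the list alone; camera, adjusted p = 0.0397, and adjusted p = 0.215 with an estimated correlation).

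**Figure D4:**
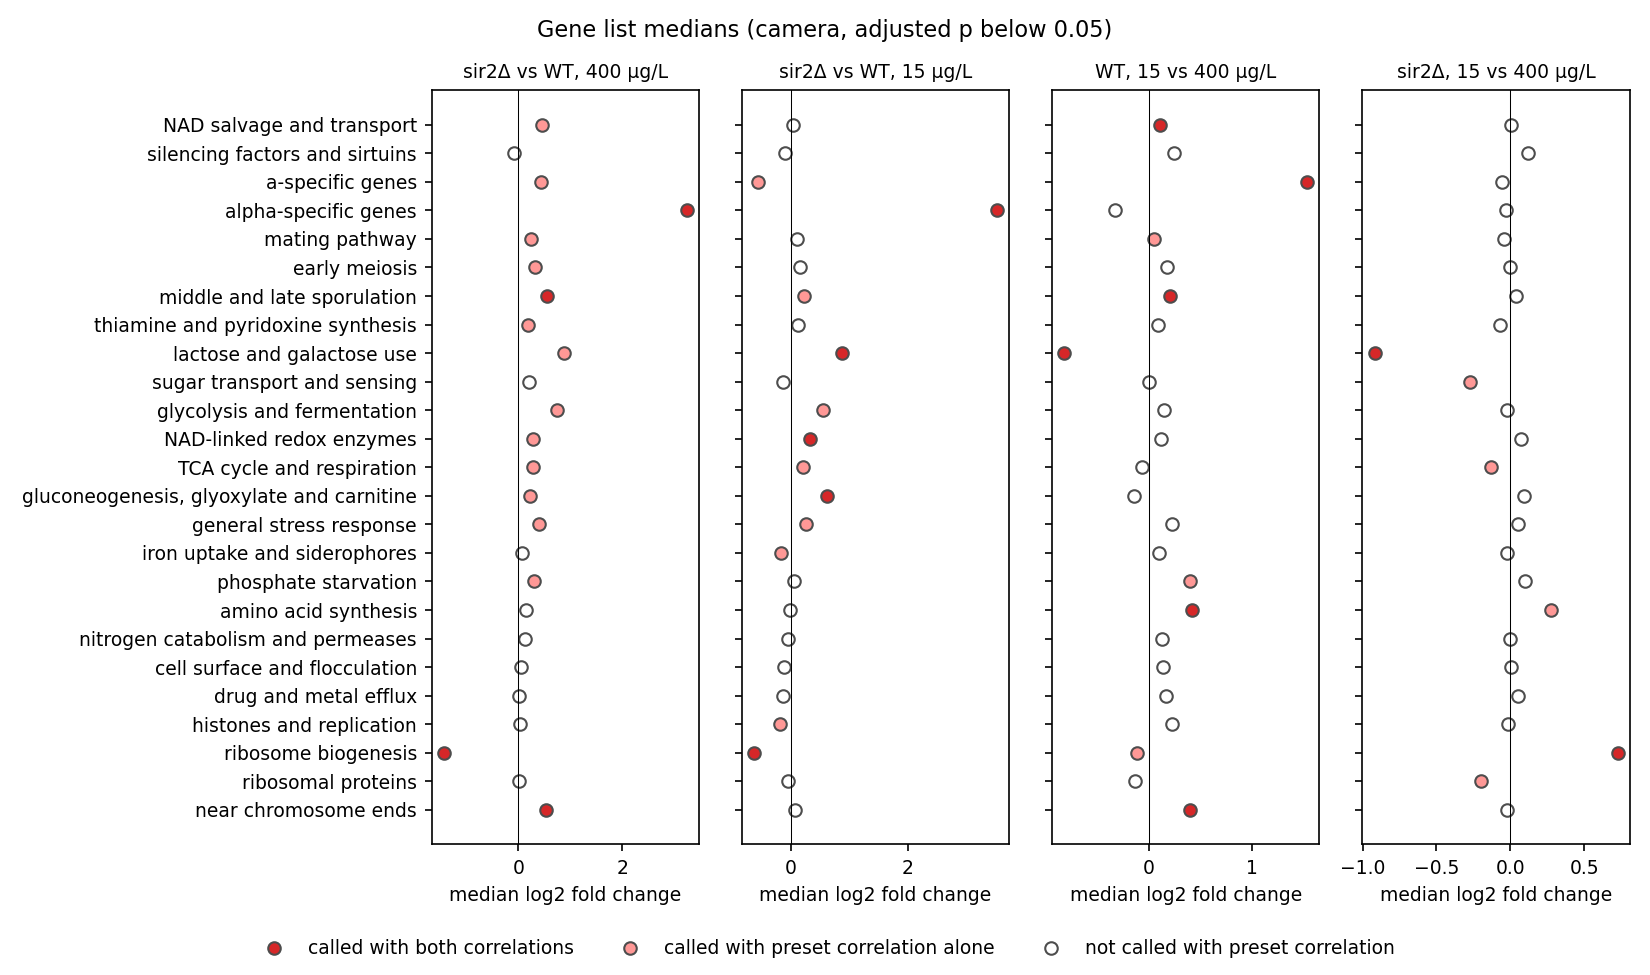
Median log2 fold change of each gene list (horizontal axis) in 4 comparisons, with lists (vertical axis) that passed camera with the preset and the estimated correlation in dark red, with the preset one alone in light red, and others in white. Ribosome biogenesis has medians of -1.43 in sir2Δ against WT at 400 µg/L, -0.63 at 15 µg/L, -0.12 in WT and 0.73 in sir2Δ at 15 against 400 µg/L.

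In sir2Δ, lowering nicotinic acid from 400 to 15 µg/L raised ribosome biogenesis genes, while TNA1 and NPT1 rose by less than 1 log2 unit. TNA1 went from 1878 ± 32.4 to 2499 ± 20.3 CPM (0.41 ± 0.09) and NPT1 from 726 ± 0.274 to 1144 ± 58.6 CPM (0.66 ± 0.08), and both rises passed the test. The NAD salvage list did not, with 4 of 14 higher and 0 lower (5 higher and 2 lower adjusted over the list alone; camera, adjusted p = 0.640). Of 127 ribosome biogenesis genes 110 rose and 0 fell (117 higher and 0 lower adjusted over the list alone), with a median of 0.73 (camera, adjusted p = 1.2e-67, and adjusted p = 0.00158 with an estimated correlation). LCP5 rose from 4.44 ± 0.332 to 12.6 ± 0.529 CPM (1.51 ± 0.20), RLP24 by 1.16 ± 0.10 and DRS1 by 1.11 ± 0.10. In all 604 genes rose and 318 fell, with 57 and 19 of them by at least 1 log2 unit. Rises were 65.5% of calls, and 79.8% with upper-quartile factors. Without single libraries the count of 922 fell to 534 and 469 (sir2Δ libraries 1 and 2 at 400 µg/L), 571 and 522 (sir2Δ libraries 7 and 8 at 15 µg/L) and 484 (WT library 1R).

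Genes near chromosome ends did not rise as a list in sir2Δ. Of the 178, 13 rose and 19 fell (13 higher and 19 lower adjusted over the list alone; camera, adjusted p = 0.319). The odds ratio was 0.592 for rises and 1.89 for falls (two-sided Fisher's exact tests, p = 0.0735 and 0.0156, adjusted p = 0.0817 and 0.0223). For falls it was 1.81 with 8 genes per end, which did not pass (Fisher's exact test, adjusted p = 0.0921), and 1.51 with 30 (adjusted p = 0.0489). Amino acid synthesis genes rose in 36 of 75 and fell in 1 (38 higher and 4 lower adjusted over the list alone), with ASN1, an asparagine synthetase, at 0.91 ± 0.08 and CPA1 at 0.90 ± 0.07 (camera, adjusted p = 3.1e-12, and adjusted p = 0.0519 with an estimated correlation). Galactose genes fell in 4 of 5 with a median of -0.92 (0 higher and 4 lower adjusted over the list alone; camera, adjusted p = 2.7e-11, and adjusted p = 0.00158 with an estimated correlation), with GAL10 at -1.42 ± 0.13, GAL1 at -0.95 ± 0.09 and GAL7 at -0.92 ± 0.10. Ribosomal protein genes fell in 6 of 57 and rose in 0 (0 higher and 0 lower adjusted over the list alone), with a median of -0.20 (camera, adjusted p = 3.5e-04, and adjusted p = 0.897 with an estimated correlation). The TCA cycle list had 12 lower and 2 higher of 43 (2 higher and 14 lower adjusted over the list alone; camera, adjusted p = 0.00190, and adjusted p = 0.613 with an estimated correlation). The sugar transport and sensing list had 3 of 6 lower and 0 higher (0 higher and 3 lower adjusted over the list alone), among them the glucose repressor MIG1 (-0.79 ± 0.09) (camera, adjusted p = 0.0140, and adjusted p = 0.535 with an estimated correlation).

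The named rises in sir2Δ were ARO5 (1.73 ± 0.10), KLLA0_B11363g (1.69), KLLA0_B09064g (1.63), KLLA0_F05775g (1.54), RBP95 (from 2.63 to 7.41 CPM), the aldehyde dehydrogenase ALD5 (1.49 ± 0.12) and KLLA0_C19437g (1.43). The acetyl-CoA synthetase ACS1 (1.92 ± 0.32) and ICL2 (1.63 ± 0.27) lost their call in a fit on only the groups compared, with edgeR adjusted p of 0.146 and 0.0892. KLLA0_D00253g (1.60) and KLLA0_B00264g (1.59) lost theirs without WT library 1R, at 0.0777 and 0.0513. The falls were KLLA0_F07348g (-1.39), PCK1, which encodes phosphoenolpyruvate carboxykinase (-1.12 ± 0.15), KLLA0_B14839g (-1.09), KLLA0_C18117g (-1.08), KLLA0_D06083g (-1.04) and KLLA0_B14883g (-1.01). KLLA0_A11110g (-1.37) lost its call without the resubmitted libraries, at 0.0659, and KLLA0_D15576g (-1.10) with libraries 1 and 1R entered separately, at 0.101. BIL1 (-0.91) lost it without either sir2Δ library at 400 µg/L, at 0.0961 and 0.137, without sir2Δ library 8 at 15 µg/L, at 0.246, and without WT library 1R, at 0.0877. At 45 µg/L 561 genes rose and 409 fell against 400 µg/L in sir2Δ, and at 135 µg/L 61 rose and 38 fell. The share of rises at these levels was 57.8% and 61.6%, and 68.6% and 78.2% with upper-quartile factors.

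The calls for sir2Δ at the middle levels depended on the coding length trend and on single libraries. With that trend removed, 745 of the 970 calls at 45 µg/L were shared in the same direction, and 1042 genes were called. At 135 µg/L 91 of the 99 calls were shared, and 185 genes were called. At 45 µg/L 970 genes were called, and 311 and 332 without sir2Δ library 1 or 2 at 400 µg/L, 350 without sir2Δ library 5 and 308 without WT library 1R. At 135 µg/L 99 genes were called, and 1 and 3 without sir2Δ library 1 or 2, 17 and 1 without sir2Δ library 3 or 4, 48 and 49 without sir2Δ library 7 or 8, 35 without either WT library at 135 µg/L, 3 without WT library 1R, 154 without either sir2Δ library at 45 µg/L and 166 without WT library 1.

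The interaction tested whether the response to 15 against 400 µg/L differed between the strains. TNA1 (-2.57 ± 0.13), NPT1 (-2.35 ± 0.12), URH1 (-1.04 ± 0.11), FUN26 (-0.65 ± 0.12) and QNS1 (-0.45 ± 0.11) had a more negative response in sir2Δ than in WT. In sir2Δ itself QNS1 rose by 0.30 ± 0.08, while URH1 (-0.10 ± 0.08) and FUN26 (-0.02 ± 0.09) did not pass the test. Of the 14 NAD salvage genes 6 had a more negative response in sir2Δ and 1 a more positive one (2 higher and 6 lower adjusted over the list alone; camera, adjusted p = 5.4e-04, and adjusted p = 0.0673 with an estimated correlation). Genes near chromosome ends went the same way in 86 of 178, with 2 the other way (5 higher and 99 lower adjusted over the list alone; median -0.44; camera, adjusted p = 1.9e-37, and adjusted p = 0.000219 with an estimated correlation), and the odds ratio was 10.2 (two-sided Fisher's exact test, p = 7.3e-42, adjusted p = 7.3e-41), with 15.8 for 8 genes per end and 5.41 for 30. KLLA0_A00132g (-4.56 ± 0.19), KLLA0_B00143g (-4.33), KLLA0_F00154g (-4.30), KLLA0_D00143g (-4.27), KLLA0_E00133g (-4.24), KLLA0_A00110g (-4.10), KLLA0_C00132g (-4.08), KLLA0_D20031g (-4.05), KLLA0_E00111g (-4.03) and KLLA0_C00110g (-3.97) had the most negative values apart from the pair KLLA0_C03157g and KLLA0_B14575g, which rest on few sir2Δ reads. In all 392 genes had a more positive and 507 a more negative response in sir2Δ. The share of positive calls was 43.6%, and 61.2% with upper-quartile factors, and the count of 899 genes was 572 without WT library 1R and 1198 without library 1.

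Lists of mating, sporulation and metabolism also differed in their response. The a-specific genes were lower in 5 of 6 and higher in 0 (0 higher and 5 lower adjusted over the list alone), with a median of -1.52 (camera, adjusted p = 1.1e-07, and adjusted p = 0.00514 with an estimated correlation), BAR1 at -2.33 ± 0.16 and STE2 at -1.46 ± 0.15. Sporulation genes were lower in 13 of 38 and higher in 1 (1 higher and 15 lower adjusted over the list alone; camera, adjusted p = 1.1e-07, and adjusted p = 0.0322 with an estimated correlation). The mating pathway had 9 of 25 lower and 0 higher (1 higher and 9 lower adjusted over the list alone), with GPA1 at -2.68 ± 0.16, STE18 at -2.36 ± 0.27 and STE4 at -2.35 ± 0.11 (camera, adjusted p = 2.4e-04, and adjusted p = 0.0673 with an estimated correlation). Thiamine genes had 4 of 10 lower and 0 higher (0 higher and 4 lower adjusted over the list alone; camera, adjusted p = 0.0120, and adjusted p = 0.0673 with an estimated correlation), and phosphate genes 4 of 16 lower and 0 higher (0 higher and 4 lower adjusted over the list alone; camera, adjusted p = 0.00212, and adjusted p = 0.174 with an estimated correlation). Ribosome biogenesis genes went the other way, 107 of 127 higher and 0 lower (117 higher and 0 lower adjusted over the list alone), with a median of 0.82 (camera, adjusted p = 2.7e-37, and adjusted p = 0.00729 with an estimated correlation). They include IMP3 (1.62 ± 0.31), RRP1 (1.61 ± 0.28) and LCP5 (1.59 ± 0.26). Gluconeogenesis genes were higher in 8 of 23 and lower in 1 (9 higher and 2 lower adjusted over the list alone; camera, adjusted p = 0.0463, and adjusted p = 0.541 with an estimated correlation). ACS1 (3.02 ± 0.45), KLLA0_B09064g (2.12 ± 0.17), the ammonium permease MEP3 (2.11 ± 0.13), NOP19 (1.80), CCM1 (1.71), RBP95 (1.55) and the small RNA SNR14 (1.58) were among the most positive. SNR14 had means of 2.66 to 5.03 CPM in the groups compared, in libraries selected for poly(A) RNA. CGR1 (1.85 ± 0.39) lost its call with a term for resubmitted libraries, at an edgeR adjusted p of 0.0530. KLLA0_C00396g (2.13 ± 0.60) lost it without WT library 1, 1R, 7 or 8, at edgeR adjusted p of 0.0553, 0.150, 0.0873 and 0.109, and without sir2Δ library 1 or 8, at 0.0578 and 0.0533. Without both WT libraries 1 and 1R it had 0.48, with an adjusted p of 0.665 by edgeR. Galactose genes, which fell in both strains, had a median of -0.07 in the interaction (camera, adjusted p = 0.932).

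Of the 1362 genes called in WT at 15 against 400 µg/L, 298 were called the same way in sir2Δ and 52 the opposite way, and 553 had a called interaction, 543 with the smaller response in sir2Δ. Among the 218 with at least 1 log2 unit in WT, 56 were called the same way in sir2Δ and 191 had a called interaction, all with the smaller response in sir2Δ. These genes were picked on WT libraries that also enter the interaction, which favours a smaller response in sir2Δ. The 201 rises among them had a median of 1.80 in WT and 0.14 in sir2Δ. The slope of the sir2Δ change on the WT change was 0.112 over the 1362 genes, and 0.0856 over the 557 genes picked at 45 µg/L, a choice that still uses the WT libraries at 400 µg/L. The number called the same way fell from 298 to 181 and 177 without sir2Δ library 1 or 2 at 400 µg/L, to 189 without sir2Δ library 7 and to 165 without WT library 1R.

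The WT response was then set against the strain difference at 400 µg/L. Of the genes called in both, 441 were higher in both and 133 lower in both, against 185 and 120.0 for independent lists, and 198 went opposite ways. Pearson's r of the log2 fold changes across genes was 0.548 and Spearman's rho 0.250, and genes are not independent replicates. The 2 comparisons share the WT libraries at 400 µg/L, and simulated unchanged groups that share them had r = 0.472, at most 1 shared call in 30 simulations, and a covariance of 0.0125 against the observed 0.220. Part of the overlap may come from the shared libraries. With the strain difference at 135 µg/L, which shares no library, 363 genes were higher in both and 77 lower in both. Independent lists would give 135 and 82.6, and 183 genes went opposite ways. Pearson's r was then 0.438, Spearman's rho 0.158 and the covariance 0.170. Of the 236 genes higher by at least 1 log2 unit in sir2Δ at 400 µg/L, 184 rose in WT at 15 µg/L and 13 fell. Of the 243 genes lower by that much, 25 fell in WT and 8 rose.

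**Figure D5:**
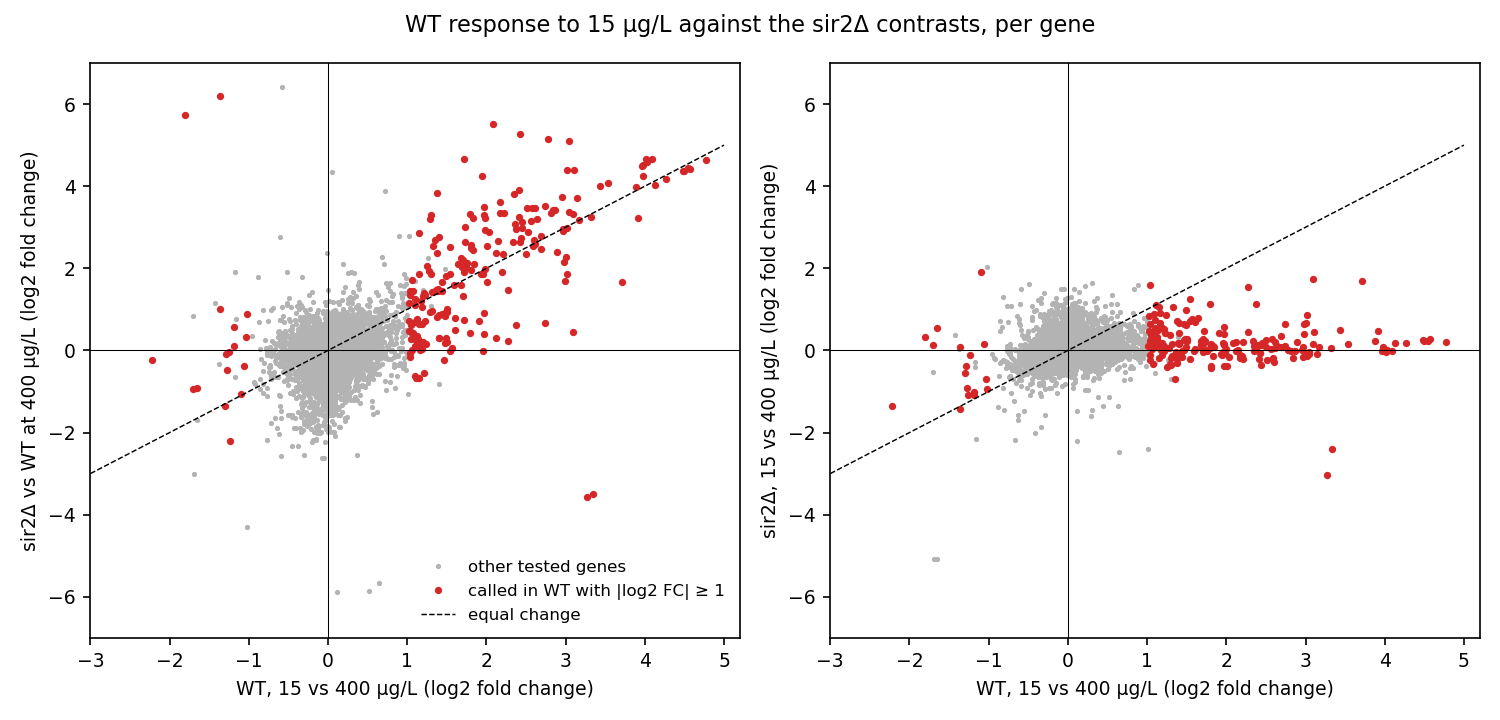
Log2 fold change per gene in WT at 15 against 400 µg/L (horizontal axis) against sir2Δ versus WT at 400 µg/L (left panel) and sir2Δ at 15 against 400 µg/L (right panel), with genes called in WT at 1 log2 unit or more in red and dashed lines of equal change. Of these 218 genes, 178 were called the same way on the left and 56 on the right.

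Several lists did not pass camera at 400 µg/L between strains or in WT at 15 against 400 µg/L. Silencing factors and sirtuins had 2 higher and 3 lower of 13 in sir2Δ (2 higher and 3 lower adjusted over the list alone; camera, adjusted p = 0.627) and 6 and 0 in WT (7 higher and 0 lower adjusted over the list alone; adjusted p = 0.231), with the sirtuin HST2 at -1.13 ± 0.27 and RIF1 at -0.67 ± 0.08 between strains and the repressor SUM1 at 0.73 ± 0.11 in WT. Nitrogen genes had 11 higher and 8 lower of 30 between strains (12 higher and 8 lower adjusted over the list alone; camera, adjusted p = 0.565) and 10 and 4 in WT (11 higher and 6 lower adjusted over the list alone; adjusted p = 0.588). Cell surface genes had 2 and 2 of 14 (2 higher and 2 lower adjusted over the list alone; camera, adjusted p = 0.779) and 3 and 0 (3 higher and 0 lower adjusted over the list alone; adjusted p = 0.112), with the mannoprotein CWP1 at 1.60 ± 0.10 and 1.68 ± 0.10. Drug and metal efflux genes had 5 and 4 of 18 (5 higher and 4 lower adjusted over the list alone; camera, adjusted p = 0.435) and 7 and 2 (7 higher and 2 lower adjusted over the list alone; adjusted p = 0.0997), with the arsenate reductase ARR2 at 2.34 ± 0.23 and 2.51 ± 0.23.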

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

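The tests of library 1 of WT at 400 µg/L, of shared libraries and of scaling were chosen after those results were seen, and the predictions of the other tests in this part were written before. Removal of the coding length trend, which 1 of those tests uses, was itself chosen after the data were seen. The gap test for single outlying samples needs groups of at least 4, so it was not applied to these groups of 2 or 3 libraries.

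The response to 15 against 400 µg/L differed between sir2Δ and WT for 899 genes by the interaction test. Among the genes with a more positive response in sir2Δ, the log2 difference was 3.02 for ACS1, 2.13 for KLLA0_C00396g, 2.12 for KLLA0_B09064g, 2.11 for MEP3, 1.85 for CGR1 and 1.80 for NOP19. It was 1.71 for CCM1, 1.62 for IMP3, 1.61 for RRP1, 1.59 for LCP5, 1.58 for SNR14 and 1.55 for RBP95. With a more negative response, KLLA0_C03157g had -6.31, KLLA0_B14575g -5.73, KLLA0_A00132g -4.56, KLLA0_B00143g -4.33, KLLA0_F00154g -4.30 and KLLA0_D00143g -4.27. KLLA0_E00133g had -4.24, KLLA0_A00110g -4.10, KLLA0_C00132g -4.08, KLLA0_D20031g -4.05, KLLA0_E00111g -4.03 and KLLA0_C00110g -3.97. The values of KLLA0_C03157g and KLLA0_B14575g rest on few sir2Δ reads. KLLA0_C00396g lost its call with DESeq2, and its difference was 0.48 without WT libraries 1 and 1R. Gene lists that passed camera in the interaction had medians of -0.11 for NAD salvage and transport, -1.52 for a-specific genes, -0.28 for the mating pathway, -0.30 for sporulation, -0.12 for thiamine, 0.23 for gluconeogenesis, -0.14 for phosphate, 0.82 for ribosome biogenesis and -0.44 for genes near chromosome ends. By camera, 5 of these lists lost their call with an estimated correlation, at an adjusted p = 0.0673 with an estimated correlation for NAD salvage, the mating pathway and thiamine, 0.174 for phosphate and 0.541 for gluconeogenesis.

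Library 1 of WT at 400 µg/L stood apart from libraries 1R and 2. Its log2 difference from their mean had a Spearman rho of -0.71 with coding length across genes, against 0.12 for 1R minus 2, so a length-dependent difference in preparation or RNA quality is a candidate source. Admixture of sir2Δ RNA as the source is argued against by its share over 62 genes, estimated against library 2, with a median of -0.698% for library 1 minus 1R (quartiles -1.50% and 1.10%). The shares themselves had medians of 1.32% in library 1 and 2.12% in 1R, so a small share common to both is not excluded. What made the length trend was not tested, and no biological explanation was tested.

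Ribosome biogenesis genes had a median log2 fold change of -1.43 in sir2Δ against WT at 400 µg/L, with an SD of 0.433 over 127 members. A length trend as the whole cause is argued against by a median of -1.42 after its removal, library 1 by -1.03 at 135 µg/L, where it takes no part, and scaling, which shifts all genes alike, by -1.43 for the list minus the median of the other genes. A difference due to SIR2 or to mating type stays open as untested, since the design does not separate them.

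Genes that rose in WT at 15 µg/L were often higher in sir2Δ than WT at 400 µg/L, 441 of 823 against 185 for independent lists. This did not extend to the falls, of which 133 of 539 were lower, against 120.0, and at 135 µg/L, with no library in common, 77 were, against 82.6. Shared libraries as the whole cause are argued against by a covariance of 0.170 with no library in common, against 0.220 with shared ones. A few repeat families near chromosome ends as the whole cause are argued against by Pearson's r = 0.370 across genes with no library in common and without the end genes. Spearman's rho was 0.130 there and 0.158 with the end genes, so across ranks the relation was weak with or without them. Lower Sir2 activity in WT at 15 µg/L stays an untested hypothesis for the rises, since mating type differs between the strains, and a MATa strain lacking SIR2 and a measure of Sir2 activity at 15 µg/L would test it.

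For sir2Δ against WT averaged over the 4 levels, 1 of 100 drawn splits that kept 2 libraries per arm at each level, the real one, called as many genes as the 3195 observed. Only 100 of 648 possible splits were drawn, so a share under 1 in 100 could not be shown. The highest of the other splits called 2350 genes and had 2 libraries in the wrong arm. All drawn splits with 2 in the wrong arm called at least 1954 genes, and the remaining ones at most 214.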

How the results depend on the processing

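The removal of a coding length trend, the tests with 8 or 30 genes per end, without near-identical families or without the 3 genes placed at HML, and the overlap without library 1 were chosen after the data were seen, and the other alternatives were set before. Of 3719 results for named genes under the alternatives, 3674 kept their call and direction, 45 lost the call and 0 reversed. These genes were picked as the largest called changes in the same libraries, which favours keeping the call. Distances of 10 and 50 kb from chromosome ends were not run, because no coordinates were used. Where a left-out library leaves 1 in its group, that sample is assumed to vary like the other groups. The cause was not tested for any of the changes below, except that a fold change minimum lowers counts by construction. Depth limits the genes with few reads in 1 strain, whose fold changes depend on the prior count.

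With libraries 1 and 1R entered separately, the genes called in sir2Δ against WT numbered 1080 at 135 and 976 at 15 µg/L, in WT 338 at 45 and 68 at 135 µg/L, in sir2Δ 444 at 15, 275 at 45 and 3 at 135 µg/L, and in the interaction 570, and 148 of the WT genes were called the same way in sir2Δ. With a term for resubmitted libraries WT at 135 µg/L had 96. Without the resubmitted libraries WT had 329 at 45 and 80 at 135 µg/L, sir2Δ 591 at 15 µg/L, and 180 WT genes were called the same way in sir2Δ.

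Same-number correlations between strains were -0.0800 at 400, -0.0130 at 135, 0.490 at 45 and 0.246 at 15 µg/L. They were positive at only 2 of the 4 levels, so the numbers were not taken to pair the samples, although at 45 µg/L libraries 5 and 6 differed with coding length in both strains (Spearman rho 0.53 in WT and 0.64 in sir2Δ). With the number as a block, 250.0 genes were called in WT and 270.0 in sir2Δ at 135 µg/L, and other counts stayed within 1.5 times. The block ended the calls of ACS1 in WT (edgeR, adjusted p = 0.0827), KLLA0_A11110g in sir2Δ (0.0590) and KLLA0_C00396g in the interaction (0.168).

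With a log2 fold change of at least 1, sir2Δ against WT had 479 at 400, 333 at 135, 389 at 45, 133 at 15 µg/L and 330 on average, WT had 218, 79 and 12 and sir2Δ 76, 24 and 13 at 15, 45 and 135 µg/L, the interaction 249, the overlap of WT response and strain difference 141, and 15 WT genes were called the same way in sir2Δ. With a length trend removed WT had 928 at 45 and 292 at 135 µg/L, sir2Δ 185 at 135 µg/L, and 463 WT genes were called the same way in sir2Δ. Fitted on only the groups compared, the strains differed in 2879 genes at 135 and 1345 at 45 µg/L, WT had 865 at 15, 153 at 45 and 32 at 135 µg/L, and sir2Δ 1527 at 15 and 1010 at 135 µg/L. With DESeq2 WT had 268 and sir2Δ 261 at 135 µg/L. Of the genes picked in WT at 45 µg/L, 153 were called the same way in sir2Δ.

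Camera with an estimated correlation called 4 lists between strains at 400 µg/L, 5 at 15 µg/L, 2 in sir2Δ and 4 in the interaction, and fry called 20 in WT, 10 in sir2Δ and 18 in the interaction.

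Over the 18 settings that leave out a library, the counts ranged from 1649 to 2921 for the strains at 400 µg/L, 1083 to 1872 at 135, 1540 to 2258 at 45, 1029 to 1797 at 15 and 2581 to 3424 on average. They ranged from 841 to 1584, 319 to 670 and 35 to 293 in WT and from 469 to 1116, 308 to 1251 and 1 to 166 in sir2Δ at 15, 45 and 135 µg/L, and from 572 to 1198 for the interaction. The overlap ranged from 429 to 811, the WT genes called the same way in sir2Δ from 165 to 351, and the odds ratio of genes near ends in WT from 6.74 to 7.94. The number of genes per end moved that odds ratio more, to 12.1 with 8 and 4.06 with 30 in place of 7.66, and it was 6.36 without near-identical families and 7.97 without the 3 genes placed at HML. Between strains at 400 µg/L it was 9.86 with 8 and 2.91 with 30 in place of 6.08, in the interaction 15.8 and 5.41 in place of 10.2, and between strains at 15 µg/L 2.98 and 1.37 in place of 2.09. For falls in sir2Δ it was 1.81 with 8, which lost the call (Fisher's exact test, adjusted p = 0.0921), and 1.51 with 30 in place of 1.89.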

Other observations

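Galactose genes fell at 15 against 400 µg/L in each strain, with a median log2 fold change of -0.81 in WT and -0.92 in sir2Δ. The 5 measured members of the lactose and galactose list are all GAL genes, and 4 were lower in each strain (edgeR quasi-likelihood test). GAL10 had 141 ± 22.9 CPM at 400 and 54.5 ± 2.74 at 15 µg/L in WT, and 282 ± 4.33 and 106 ± 10.6 in sir2Δ (n = 2 each).

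The comparison of sir2Δ at 400 µg/L with WT at 15 µg/L and the correlations with coding length were chosen after the data were seen. Among the 201 genes that rose by at least 1 log2 unit in WT at 15 µg/L, the level in sir2Δ at 400 µg/L was above the WT level at 15 µg/L for 75 and below it for 72 by the edgeR test, with a median log2 difference of 0.06. Of these genes 43 lie among the 15 nearest to a chromosome end. Across genes, the log2 fold change had a Spearman rho with coding length of 0.45 in sir2Δ at 45 against 400 µg/L and 0.42 at 135 µg/L, and 0.32 in WT at 135 µg/L. The rho was 0.24 in sir2Δ at 15 against 400 µg/L and -0.21 in sir2Δ against WT at 400 µg/L.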
